A study of Mus musculus with 10 samples.

How the data were processed

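Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, in thymic epithelial cells (TEC) of wild-type C57BL/6 mice. Per the labels, thymus tissue was digested with the enzyme mix Liberase TH and with DNase, TEC were obtained by sorting, and libraries were made with a modified ATAC-seq protocol. The 10 libraries fall into 5 groups of 2: embryonic day 15 (E15), embryonic day 17 (E17), and the day 6 fractions labelled mTEC4, mTEC1 and mTEC2. The titles do not spell out the fraction names, and those of the embryonic libraries name no fraction. Peak names inside the lists use other fraction names than the titles. There, the E15, E17 and mTEC2 lists share a tag that the mTEC4 and mTEC1 lists lack. Groups were taken from the titles.

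Per the submitters' processing notes, cutadapt, Bowtie2, Picard and MACS2 were used with the mouse build mm10, with no versions or order given, and whether read ends were shifted for the transposase is not given in the sources used here. The authors deposited 1 broad peak list per library, so replicates were not pooled, and per the labels these lists describe nucleosome-free chromatin. Each deposited peak carries a score, which the values show to be 10 times the −log10 q with decimals dropped and which was not used here. The fold enrichment deposited for each peak is a ratio to the caller's own background within that library. The −log10 p and −log10 q of each peak were also calculated by the authors' caller. In these lists −log10 q was never below 1.0002, a q of at most 0.1. Folds and q values belong to their own list, so they served only to describe, rank or filter peaks within a list, and lists were compared by presence or absence of peaks. The lists carry no read counts, so the read depth of each library is unknown and no counting interval is given for a locus. A missing peak means that none was called, not that the site was closed.

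Gene positions came from a RefSeq gene table of the same build, with the start and end of 21887 protein-coding genes but no strand, exons or transcripts. A peak was therefore placed at a gene boundary (within 1 kb of either end of a gene), inside a gene span, or elsewhere. The intended transcription start sites were replaced by gene ends and spans for this reason. No genome sequence was used, so the planned scores of 22 transcription factor motifs and their alternatives were not run.

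All peaks were merged into regions where they overlapped by 1 bp or touched, and a region counted as called in a library with any overlapping peak. Similarity of 2 lists was the Jaccard index, the sequence shared as a percent of the sequence covered by either. Regions called in exactly 4 or exactly 6 libraries were tested for embryonic against day 6 calls with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment. Library measures were compared by exact permutation over the 210 ways to choose 4 of 10 libraries, and each group by the 45 ways to choose 2. In the 2 against 2 comparison of E15 and E17 no test can reach 0.05, nor can one for 2 of the 6 day 6 libraries, where the smallest p is 0.0667. For a group of 2 of the 10 libraries the smallest p is 0.0222, which for 1 list alone gives an adjusted p of 0.489 over 22 lists, so a count of 0 list scores past the threshold says nothing about such a group.

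A gene list score was the log2 ratio of the mean number of called regions per listed gene (gene span with 10 kb on each side) to the same mean over all protein-coding genes of that library, with 0.1 added to each mean. The score corrects for the number of called regions, though not for its interplay with peak strength. The 22 lists covered TEC identity and cortical TEC, thymus organogenesis factors, epithelial genes, Ccl21a-high medullary TEC, Aire-stage medullary TEC, the NF-kB pathway, post-Aire keratinocyte-like TEC, tuft, microfold, endocrine, ciliated, enterocyte and hepatocyte, muscle and parathyroid cells, thymocytes and T cells, dendritic cells and macrophages, B cells, erythroid cells, endothelium, mesenchyme, cell cycle and housekeeping genes. Of 296 listed symbols, 1 was not matched (Loricrin) and 2 were matched through older symbols. Enrichment of a list among genes nearest to specific regions (within 100 kb) was tested by a permutation against 10000 random gene lists matched on background regions per gene, one-sided, with a smallest possible p of 0.0001. The background held regions called in both libraries of at least 1 group compared. These enrichment tests describe the region sets, not the spread between replicates.

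Named genes followed a rule. Foxn1, Aire, Psmb11, Ccl21a, Pou2f3 and Trp63 were always named, together with up to 15 listed genes with the most specific regions and the 10 specific regions of highest within-list strength for each comparison and direction. Some genes that the rule selects are not reported here. The groups, lists, tests, naming rule and most alternatives were fixed before the data were examined. Alternatives were a −log10 q of at least 5, equal list lengths of 40858 peaks, a 50% cover of regions, other overlap measures, other distances to genes, a larger added constant, leaving out each library and permuting within replicate numbers. An equal number of 4375 strongest peaks, autosomes only, and leaving out mTEC4 replicate 1 and mTEC1 replicate 1 together were added after the lists had been seen. Other ways to divide the E15 and E17 libraries, and to pair the day 6 libraries, were counted in these alternatives only after results were seen.

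Replicate lists shared 72 to 297 peaks with identical coordinates per group, out of list lengths of at least 40858 peaks, so no library had been deposited more than once. Nothing in the labels says that replicates came from separate animals or litters, so p-values measure the spread between libraries, which may be technical. Tests on simulated data recovered 200 of 200 planted regions that separated the embryonic and day 6 libraries among 351411. With library calls drawn independently, 700 other regions separated by chance against 743 expected, and 0 of all these passed the adjusted threshold. A planted list score of 1 on the log2 scale was recovered as 0.92 and called before adjustment, with 0 of the other 21 lists called. After adjustment 0 of the 22 lists passed, so the planted list itself was missed at the adjusted threshold. A list score short of that threshold therefore does not show that a difference is absent. The planted enrichment was recovered along with 1 list that had not been planted. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, with the random seed 20240.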

Results

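The series concerns the transcriptional regulation of Foxn1, the forkhead transcription factor required for thymic epithelial development. Open chromatin was profiled in sorted TEC at E15 and E17 and in 3 fractions taken at day 6, with 2 libraries in each of the 5 groups. The 10 peak lists held 882163 peaks. There were 105204 and 101357 peaks in the E15 lists and 86237 and 151646 in the E17 lists. At day 6 the mTEC4 lists held 70144 and 71192 peaks, the mTEC1 lists 82281 and 71327, and the mTEC2 lists 101917 and 40858. Read depth is unknown, so a longer list may reflect deeper sequencing as well as more open chromatin. Age and sorted fraction differ together between the embryonic and the day 6 libraries, and the comparisons between them cover both.

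The comparison at Foxn1 asked where chromatin was open around the gene. Foxn1 spans 78357577 to 78386783 on chromosome 11 (mm10, RefSeq). Within 50 kb of it, 30 regions were called, and the embryonic libraries had more of them than the day 6 libraries, with 19.8 ± 2.87 (SD, n = 4) against 7.67 ± 4.37 (SD, n = 6). Inside the gene span the embryonic libraries had 5, 6, 6 and 7 regions. The mTEC1 libraries had 1 and 5, both mTEC2 libraries had 2, and neither mTEC4 library had any. The widest internal region, at 78373922 to 78375128, was called in all 4 embryonic libraries, in both mTEC1 libraries and in 1 mTEC2 library. Regions at 78358461 to 78358879, near the low-coordinate end of the gene, and at 78386154 to 78387050, across its high-coordinate end, were called in all 4 embryonic libraries and in no day 6 library. A region at 78360606 to 78360817 was called in all 4 embryonic libraries, 1 mTEC1 library and 1 mTEC2 library, and one at 78382723 to 78383022 in all 4 embryonic libraries and 1 mTEC2 library. Of the 30 regions, 17 were called in all 4 embryonic libraries. At 78327943 to 78329067, over an end of the neighbouring gene Pigs, a region was called in all 10 libraries. The table of genes has no strand, exons or introns, so these regions are not assigned to a promoter or an intron.

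The difference of 12.1 regions in the Foxn1 window had an exact two-sided permutation p of 0.00952 (n = 4 and n = 6), or 0.0175 adjusted over 11 library measures. With each list shortened to its 40858 strongest peaks the difference was 2.08 regions (exact permutation p = 0.21), and with 4375 it was -0.25 (exact permutation p = 0.571).

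**Figure D1:**
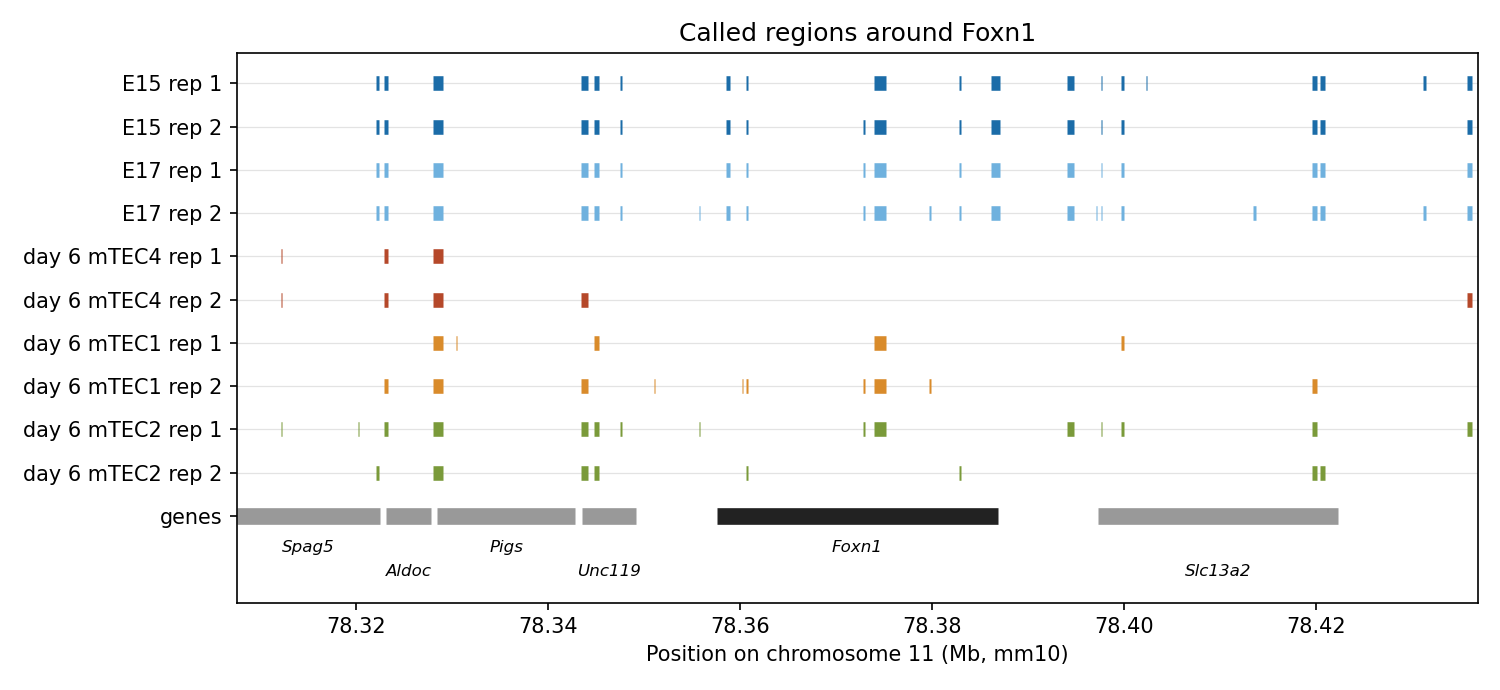
Called regions around Foxn1 on chromosome 11 (mm10), position in Mb on the horizontal axis and 1 line per library. The span of Foxn1 holds 5 to 7 regions in each embryonic library and 0 in both mTEC4 libraries.

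Loci of 5 other TEC genes were examined in the same way, counting regions in the gene span with 10 kb on each side. Trp63, which encodes the epithelial transcription factor p63 (chromosome 16, 25683763 to 25892088), had 22 ± 6.48 regions in embryonic libraries (SD, n = 4) and 6.17 ± 5.12 in day 6 libraries (SD, n = 6). Pou2f3, the tuft cell transcription factor (chromosome 9, 43123927 to 43205755), had 11 ± 2.16 against 4 ± 3.16. Aire, the regulator of tissue-restricted antigens (chromosome 10, 78030022 to 78043610), had 4.5 ± 1 against 2.5 ± 0.837. Foxn1 itself had 8.25 ± 1.26 against 2.33 ± 2.58, with a mean of 3.5 in mTEC1 and in mTEC2 and 0 in mTEC4. These 4 genes differed in region counts, which are not corrected for list length, with exact two-sided permutation p of 0.00952 to 0.0190 and an adjusted p of 0.0286 over the 6 genes.

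Psmb11, which encodes the thymoproteasome subunit of cortical TEC (chromosome 14, 54625310 to 54629556), had 3.25 ± 1.5 regions against 1.33 ± 0.816 (SD, n = 4 and n = 6; exact two-sided permutation p = 0.0476, adjusted p = 0.0571). Ccl21a, a chemokine gene (chromosome 4, 42772860 to 42773991), had 4.5 ± 0.577 against 3.17 ± 1.47 (exact two-sided permutation p = 0.152). Both mTEC1 libraries had 5 regions at Ccl21a, both mTEC4 libraries had 2, and the mTEC2 libraries had 3 and 2. Over all genes, embryonic libraries had a mean of 3.54 to 5.64 regions per gene and day 6 libraries 1.68 to 3.55. As a percentile, the percent of genes of like length with fewer regions, Foxn1 averaged 93.1 in embryonic and 39.5 in day 6 libraries. Trp63 stood at 85.9 and 41.8, Pou2f3 at 83.0 and 49.1, Aire at 68.6 and 56.9, Psmb11 at 58.2 and 35.9 and Ccl21a at 97.6 and 94.1. Ties, frequent at low counts, lower these values. For Foxn1 the day 6 values ran from 0 in both mTEC4 libraries to 96.2 in mTEC1 replicate 2, and the embryonic values from 88.7 to 95.4. Counting genes with as many regions too, Aire stood at 68.6 to 91.2 in embryonic and 51.3 to 95.5 in day 6 libraries. These percentiles were not tested.

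Across the genome, embryonic lists held wider peaks and more peaks of low q, a value that also depends on read depth. Peaks with a −log10 q of at least 5 made up 45.01 ± 3.16% of the embryonic lists (SD, n = 4) and 10.7 ± 2.78% of the day 6 lists (SD, n = 6). Median peak width was 190 ± 7.09 bp against 117 ± 9.65 bp. Peaks inside gene spans made up 43.2 ± 1.11% against 32.3 ± 4.17%, and those away from genes 41.0 ± 1.43% against 51.2 ± 7.04%. Peaks at gene boundaries, where promoters lie, made up 15.8 ± 2.52% against 16.5 ± 4.21%. Chromosome X held 2.40 ± 0.112% of embryonic and 4.83 ± 1.34% of day 6 peaks, and chromosome Y 110 ± 22.8 against 826 ± 456 peaks. By exact two-sided permutation tests (n = 4 and n = 6) the shares of strong peaks and of peaks inside genes and the median width each had p = 0.00476 and an adjusted p of 0.0105. For peaks away from genes these were 0.0238 and 0.0262, for chromosome X 0.0143 and 0.0224, and for chromosome Y 0.0190 and 0.0233. List length itself, at 111111 ± 28236 against 72953 ± 19848 peaks, had an exact permutation p of 0.0190 and an adjusted p of 0.0233.

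The difference in the gene boundary share was -0.684 percentage points (exact two-sided permutation p = 0.805, n = 4 and n = 6). By group this share averaged 16.4% in E15, 15.2% in E17, 15.2% in mTEC4, 15.2% in mTEC1 and 19.2% in mTEC2, and the groups set against the other 8 libraries had exact permutation p of 0.222 to 0.978 (n = 2). Among peaks with a −log10 q of at least 5 the boundary share was 24.4% in embryonic and 51.9% in day 6 lists, a difference of -27.5 points (exact permutation p = 0.00476, n = 4 and n = 6). These sets of peaks differed in size. With the 4375 strongest peaks of each list the shares were 44.9% and 57.9%, a difference of -13.1 points (exact permutation p = 0.205, n = 4 and n = 6).

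**Figure D2:**
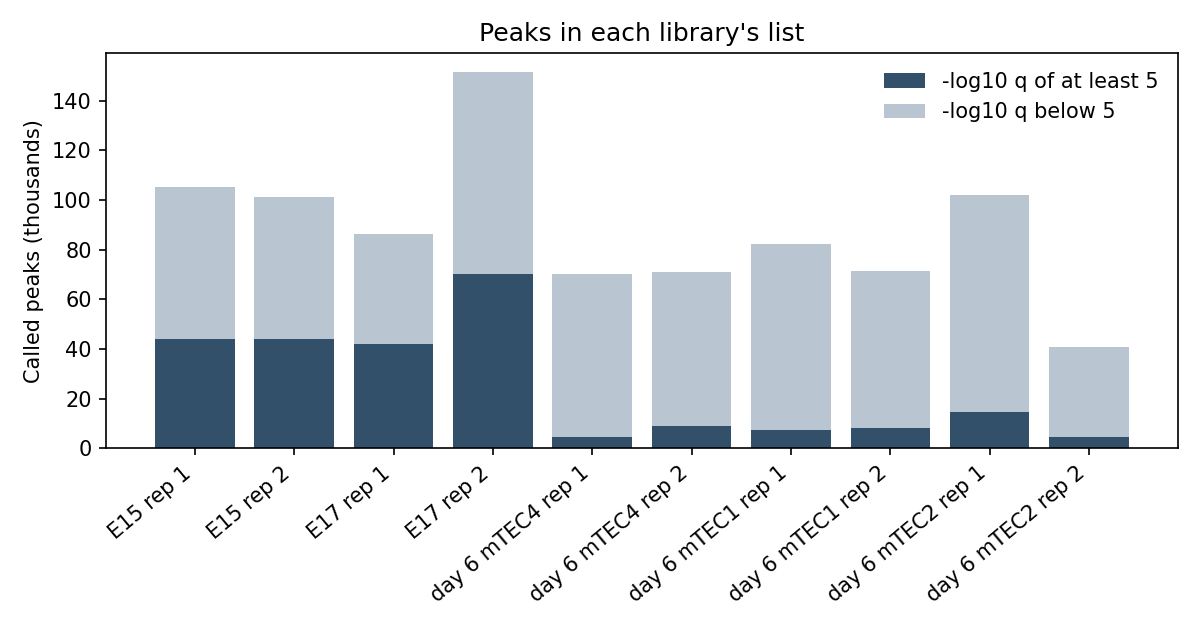
Peaks per library (vertical axis, count), divided into peaks with a −log10 q of at least 5 and weaker ones. Embryonic lists hold 42064 to 70243 strong peaks and day 6 lists 4375 to 14533.

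Over all libraries, pairs of the same group were more alike than other pairs, but within an age they hardly were. All same-group pairs share an age, while 24 of the other pairs cross ages, with a mean Jaccard index of 15.3%. The pairings tested over all libraries did not hold age fixed. The mean Jaccard index of the 5 same-group pairs was 31.4%, against 19.6% for the other 40 pairs, a difference of 11.8 percentage points (exact one-sided permutation p = 0.0180 over 945 pairings). Embryonic libraries overlapped by 45.5 to 57.2% and embryonic with day 6 libraries by 5.99 to 27.4%. The overlap with embryonic lists averaged 11.3% for mTEC4, 15.4% for mTEC1 and 19.2% for mTEC2. Within an age, same-group pairs averaged 51.3% against 50.6% among the embryonic libraries (exact permutation p = 0.333, the smallest 3 pairings can give) and 18.1% against 17.7% among the day 6 libraries (exact permutation p = 0.467). The difference over all libraries was 6.68 points without E15 replicate 1 (exact permutation p = 0.162), 6.74 points without E15 replicate 2 (p = 0.162) and 8.57 points without E17 replicate 2 (p = 0.0857).

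**Figure D3:**
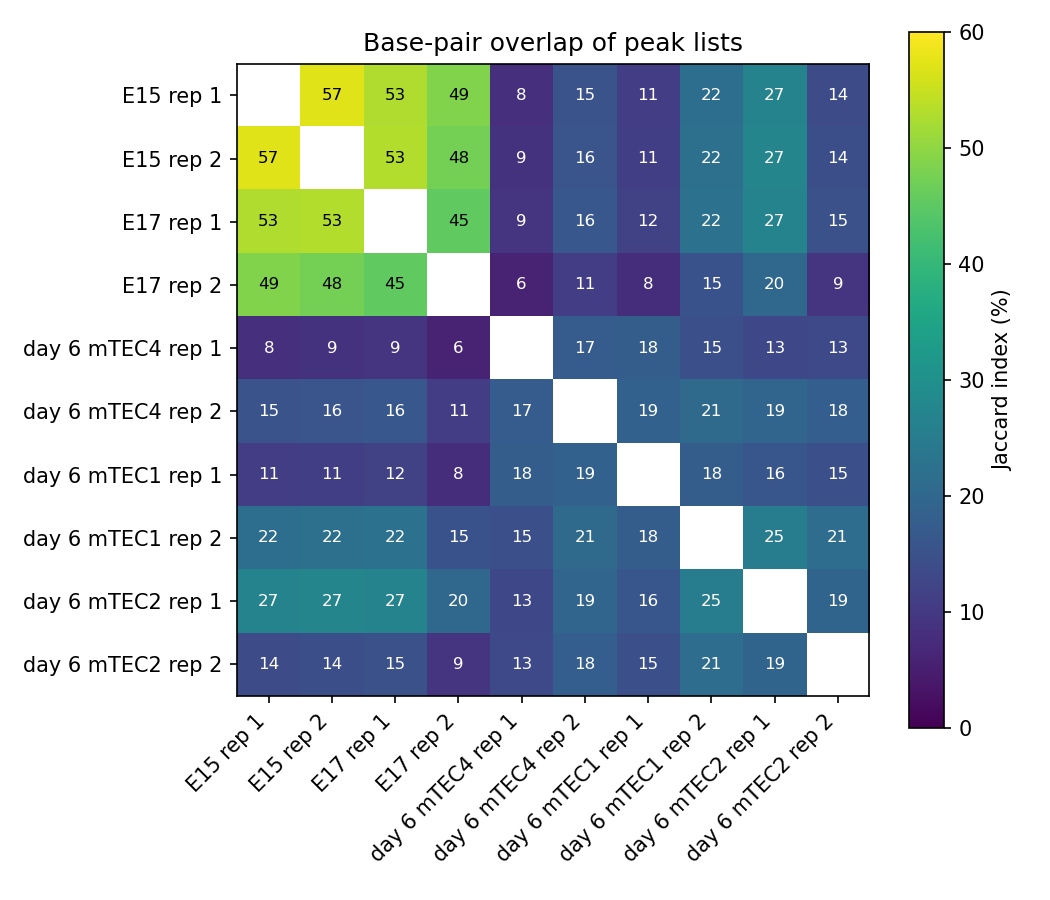
Base-pair Jaccard index (percent) of each pair of the 10 peak lists. The 4 embryonic libraries form a block at 45.5 to 57.2%, while the 3 same-group day 6 pairs lie at 17.4 to 19.3%.

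Merging gave 351411 regions, of which 15077 were called in all 4 embryonic libraries and no day 6 library, and 155 in all 6 day 6 libraries and no embryonic one. Specific regions were counted for the nearest gene within 100 kb and can lie far outside it. Among listed genes, Kitl, which encodes stem cell factor, had the most embryonic-only regions, at 7. Cxcl12, a chemokine gene, the endothelial factor gene Erg and the B cell factor gene Ebf1 had 6 each. There were 5 at Nfkb1, an NF-kB subunit gene, at Bcl11b, which encodes a T cell transcription factor, and at Ywhaz. Il7, which encodes a cytokine needed by developing T cells, Tnfrsf11a, which encodes RANK, and Flt1 had 4 each, while Traf3, Dclk1, Dnah9 and Esrp1 had 3 each. The strongest of these for Kitl lay inside the gene span on chromosome 10 at 100072535 to 100072988. For Cxcl12 it lay 73360 bp from the gene on chromosome 6 at 117254729 to 117255603. For Il7 it lay inside the gene span on chromosome 3 at 7581139 to 7581602.

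By within-list strength the leading embryonic-only region lay inside Wif1, which encodes a secreted WNT inhibitor, on chromosome 10 at 121055509 to 121055862, with a −log10 q of up to 47.1. The next lay inside Deup1, a gene of centriole amplification, on chromosome 9 at 15595475 to 15595721, followed by regions nearest to Aadat, Arhgap21, Pou1f1, Ankrd44, Prss56, Kif16b, Cd55b and Rpl38. Of the day-6-only regions 1 lay nearest to a listed gene, the T cell factor gene Tcf7, on chromosome 11 at 52275421 to 52275696. The leading day-6-only region was 86 bp wide and lay inside Ppp2r2b on chromosome 18 at 42913927 to 42914012, with a −log10 q of up to 102. Others lay nearest to Gm35315, Epha3, 4931408C20Rik, En1, Nyx, Gm21745 and Rab11a.

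Of the embryonic-only regions 7.71% lay at gene boundaries, 49.1% inside genes and 43.2% elsewhere, against 26.0%, 37.9% and 36.0% of the 50625 regions called in all 4 embryonic libraries and at least 1 day 6 library. Of the 9700 regions called in all 10 libraries, 70.2% lay at gene boundaries. Of the 10139 regions found in all 6 day 6 libraries, 98.5% were also called in at least 1 embryonic library. In single day 6 lists, 18.9 to 55.5% of the peaks with a −log10 q under 5 lay in regions called in all 4 embryonic libraries. Of the 65702 regions found in all 4 embryonic libraries, 77.1% were called in at least 1 day 6 library. Each of the 15077 and 155 regions had by definition the smallest two-sided Fisher's exact p possible here, 0.00476. The adjusted p was 0.0116 over the 37119 regions called in exactly 4 or exactly 6 libraries. It follows from the number of separating regions, which list length affects, and is not evidence for any single region. At equal list lengths the embryonic-only count was 3022, and with the 4375 strongest peaks of each list 143 regions were embryonic-only and 72 day-6-only. Leaving out mTEC2 replicate 1 gave 23931 embryonic-only regions. The day-6-only count was 273 without mTEC4 replicate 1, 246 without mTEC4 replicate 2, 249 without mTEC1 replicate 2 and 596 without mTEC2 replicate 2.

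Keratinocyte genes stood out among the genes nearest to embryonic-only regions. Of the 14 post-Aire keratinocyte-like genes with a background region, 10 had an embryonic-only region against 5.04 expected (one-sided permutation with random lists, p = 0.0022, adjusted p = 0.0484 over 22 lists). Krt80, a keratin gene, and Pkp1, which encodes a desmosome protein, had 2 such regions each and were chosen after their values were seen. The keratinocyte-like list was the 1 list past the threshold, and 0 lists passed with peaks of a −log10 q of at least 5, with equal list lengths or with genes within 25 kb. With the 4375 strongest peaks the keratinocyte-like list had an embryonic-only region at 0 of 4 genes and the epithelial list passed instead, with 2 of 4 genes against 0.0757 expected (one-sided permutation with random lists, adjusted p = 0.0264). The other 21 lists did not pass. Embryonic-only regions lay nearest to 10 of 14 TEC identity genes against 9.47 expected, 8 of 12 organogenesis factor genes against 8.69 and 9 of 16 NF-kB genes against 8.85. They lay nearest to 8 of 14 epithelial genes against 7.06 expected, 8 of 24 tuft cell genes against 9.57 and 1 of 8 erythroid genes against 1.44 (one-sided permutation with random lists, p of 0.392 to 0.845 for these 6 lists). For day-6-only regions 0 lists passed the same test and 0 had an unadjusted p under 0.05.

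Scores of whole gene lists put several epithelial and other lists higher in embryonic libraries. They correct for the number of called regions but not for its interplay with peak strength, and most of these lists did not pass at equal list lengths. The Ccl21a-high medullary TEC list scored 0.60 ± 0.05 on the log2 scale in embryonic libraries (SD, n = 4) and -0.06 ± 0.30 in day 6 libraries (SD, n = 6), a difference of 0.66. The epithelial list differed by 0.31 (0.54 against 0.23), the post-Aire keratinocyte-like list by 0.57 (-0.02 against -0.59) and the ciliated cell list by 0.35 (0.71 against 0.36). Muscle genes differed by 0.57 (-0.06 against -0.62) and mesenchyme genes by 0.51 (-0.15 against -0.65). The dendritic cell and macrophage list was lower in embryonic libraries by a difference of -0.56 (-0.75 against -0.19). All 4 embryonic libraries lay beyond all 6 day 6 libraries for these lists except mesenchyme. These 7 of 22 lists passed an exact two-sided permutation test over 210 arrangements, with adjusted p of 0.0349 to 0.0449, and 12 had an unadjusted p under 0.05.

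Single genes of these lists, chosen after their values were seen, had the following region counts. Ivl, which encodes the cornified envelope protein involucrin, had 4.25 ± 1.5 regions in embryonic libraries (SD, n = 4) against 0.167 ± 0.408 in day 6 libraries (SD, n = 6). The basal keratin gene Krt14 had 3.5 ± 1 against 0.667 ± 0.516, and Krt5 had 4 ± 1.41 against 0.833 ± 1.33. Myog, which encodes the muscle factor myogenin, had 4.25 ± 0.5 against 0.5 ± 0.837. Adgre1, which encodes the macrophage protein F4/80, had 0.5 ± 0.577 against 3.33 ± 2.16.

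The other 15 lists did not pass. TEC identity genes differed by 0.42 (adjusted p = 0.0873, exact permutation), organogenesis factors by 0.73 (0.0524), parathyroid genes by 0.35 (0.0524), B cell genes by 0.48 (0.0524) and thymocyte genes by -0.68 (0.0667). Aire-stage genes differed by 0.33 (0.0967), erythroid genes by -0.31 (0.150), housekeeping genes by -0.21 (0.154) and cell cycle genes by -0.14 (0.255). Microfold genes differed by 0.15 (0.376), NF-kB genes by 0.13 (0.47), tuft cell genes by 0.19 (0.518), enterocyte and hepatocyte genes by -0.10 (0.529), endocrine genes by 0.07 (0.673) and endothelial genes by 0.02 (0.914). Without E15 replicate 1, E15 replicate 2, E17 replicate 1, E17 replicate 2, mTEC4 replicate 2 or mTEC1 replicate 1, 0 lists passed, as was so with regions at gene boundaries alone, where the dendritic cell and macrophage difference was 0.13. With 1 library left out there are fewer arrangements, and the differences themselves ran from 0.55 to 0.71 for Ccl21a-high, 0.27 to 0.33 for epithelial, 0.52 to 0.68 for keratinocyte-like, 0.33 to 0.40 for ciliated, 0.44 to 0.65 for muscle, 0.41 to 0.59 for mesenchyme and -0.59 to -0.53 for dendritic cell and macrophage genes. At equal list lengths the ciliated, mesenchyme and microfold lists passed, and the other 5 of the 7 did not.

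**Figure D4:**
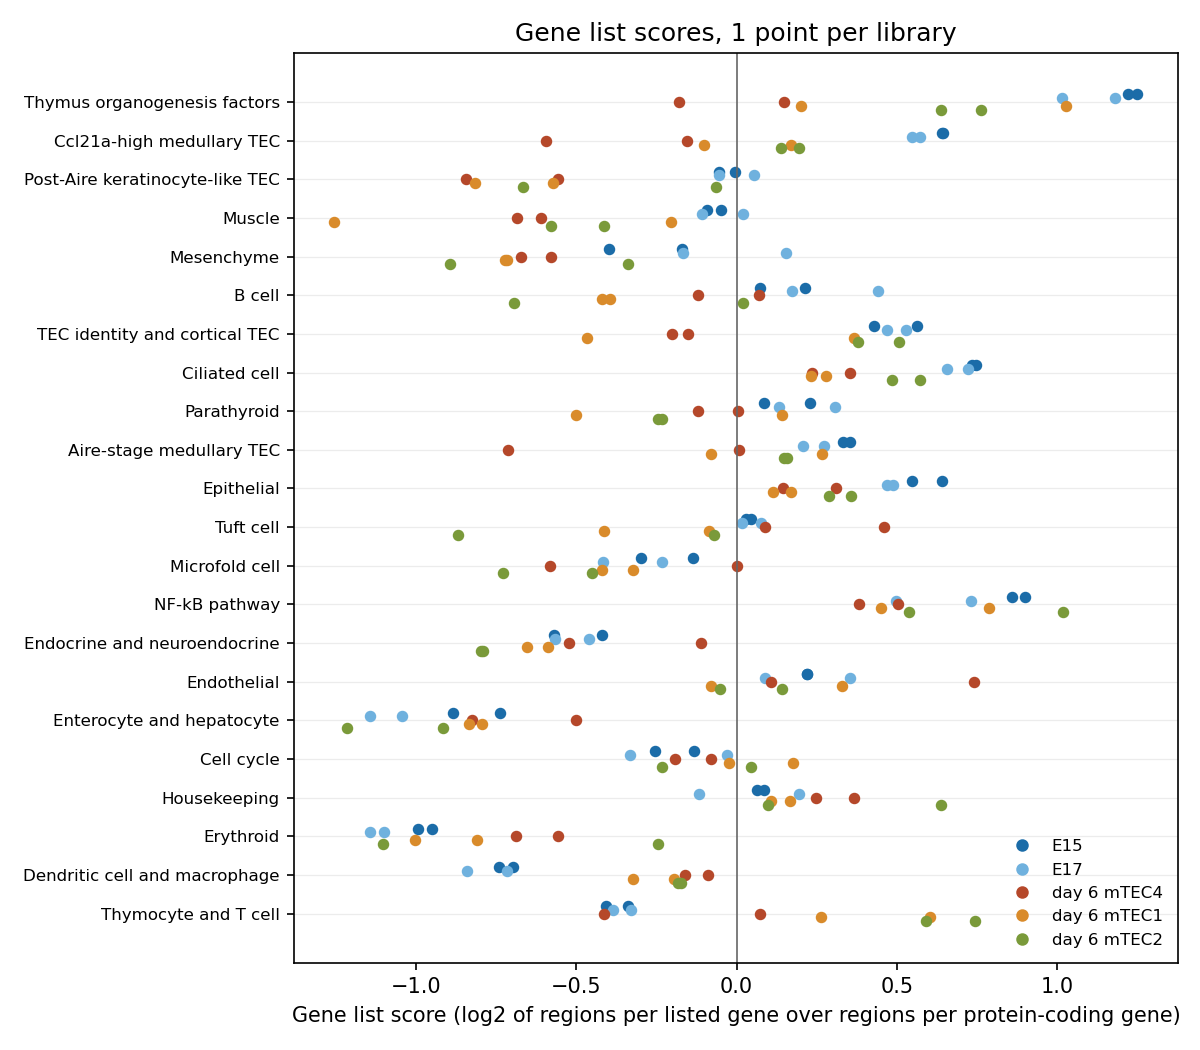
Gene list scores (log2, horizontal axis) of the 10 libraries for each list, by age and fraction. The dendritic cell and macrophage list lies at -0.84 to -0.70 in embryonic libraries and at -0.32 to -0.09 in day 6 libraries.

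Comparing the embryonic ages, Pax1, a thymus organogenesis factor gene, and the cell cycle kinase gene Cdk1 were nearest to the most regions among listed genes at E17, with 4 each. The strongest of these lay 56363 bp from Pax1 and 69589 bp from Cdk1. Col1a1, a collagen gene of mesenchyme, had 3 E17-only regions, and Col1a2 and the ciliary dynein gene Dnah5 had 2 each. Pou2f3 had 1, on chromosome 9 at 43178323 to 43178426. Tnfaip2, Dnaic1, Bcl11b, Polr2a, Gfi1b, Trpm5, Map3k14 and Ly75 also had 1 each. At E15, Lef1, a transcription factor gene of the WNT pathway, and Nfkb1 had 3 each, and Sox4, Dcn, Traf2, Birc3, Il7, Lifr and Actb had 2 each. Rgs13, Lum, Hnf4g, Foxa1, Themis and Pax1 had 1 each.

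In all, 2070 regions were called in both E15 libraries and neither E17 library, and 5071 in both E17 libraries and neither E15 library. Gene boundaries held 5.94% and 5.64% of them, against 6.44% of all regions. The leading E17-only region lay 2314 bp from Acer1, a ceramidase gene, on chromosome 17 at 56950721 to 56951175, followed by regions nearest to Gtf2a2, Ggt7, Hmga2, Npas4, Ewsr1, Cald1, Ddx6, Mrln and Rnf212b. The leading E15-only region was 77 bp wide and lay inside Immp2l on chromosome 12 at 41515116 to 41515192, followed by regions nearest to Map3k7, Fam241a, Ccng2, Mkx, Cenpw, Chst11, Bbox1, Etl4 and Vmn2r43. Of the 22 lists 0 passed the enrichment test for either age, with 1 unadjusted p under 0.05 at E15 (Aire-stage genes, 4 of 16 against 1.29 expected, permutation with random lists, p = 0.0288) and 0 at E17. Of the list scores of E15 and of E17 against the other 8 libraries, 0 passed the exact permutation test, which a single list cannot pass with 45 arrangements, and 1 and 2 had an unadjusted p under 0.05.

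In the lists as deposited, the 7141 regions that separated E15 from E17 did not exceed the 7173 and 9429 of the other 2 ways to divide these libraries. At equal list lengths they did, with 5447 against 1875 and 2047, as with the 4375 strongest peaks (2334 against 194 and 224) and with peaks of a −log10 q of at least 5 (5367 against 3381 and 3559). With 3 ways to divide the libraries no share can lie below 0.333. Without E15 replicate 1 the counts were 9395 and 10078, without E15 replicate 2 they were 9347 and 8867, and without E17 replicate 2 they were 14240 and 9117. Leaving out E17 replicate 1 gave 47910 E17-only regions. Among peaks with a −log10 q of at least 5, 704 regions were E15-only, at equal list lengths 2876 were E17-only, and with the 4375 strongest peaks the counts were 1308 and 1026.

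Among the loci of tuft cells, chemosensory epithelial cells that also occur in the thymus, some had regions exclusive to mTEC4. Regions called in both mTEC4 libraries and in no other day 6 library lay nearest to 10 of the 21 tuft cell genes with a background region, against 2.09 expected (one-sided permutation with random lists, p = 0.0001, the smallest these can give; adjusted p = 0.0022 over 22 lists). Dclk1, a kinase gene, had one on chromosome 3 at 55501436 to 55501696, and Il25, which encodes the tuft cell cytokine interleukin 25, had one on chromosome 14 at 54931506 to 54931673. The other 8 genes, chosen after their values were seen, were Chat (chromosome 14, 32422839 to 32423105), Plcb2 (chromosome 2, 118728408 to 118728887), Alox5ap (chromosome 5, 149277656 to 149278052), Gnat3, Avil, Ascl2, Gfi1b and Sh2d6. Chat encodes the enzyme that makes acetylcholine, and Gnat3 and Plcb2 belong to taste signal transduction. Of these 10 regions, 9 were called in no embryonic list. Pou2f3 had no mTEC4-specific region, with 0 and 6 regions in the mTEC4 libraries, a mean of 3 against 3.5 in mTEC1 and 5.5 in mTEC2. Trpm5, chosen after its values were seen, averaged 1.5 regions in mTEC4 against 2.5 and 2. The peaks were weak, with a −log10 q of 1.18 to 3.77. At equal list lengths 5 of 16 tuft genes had such a region against 0.887 expected (one-sided permutation with random lists, adjusted p = 0.0308), while 0 lists passed with peaks of a −log10 q of at least 5 or with the 4375 strongest peaks, where 1 and 0 tuft genes had a background region.

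**Figure D5:**
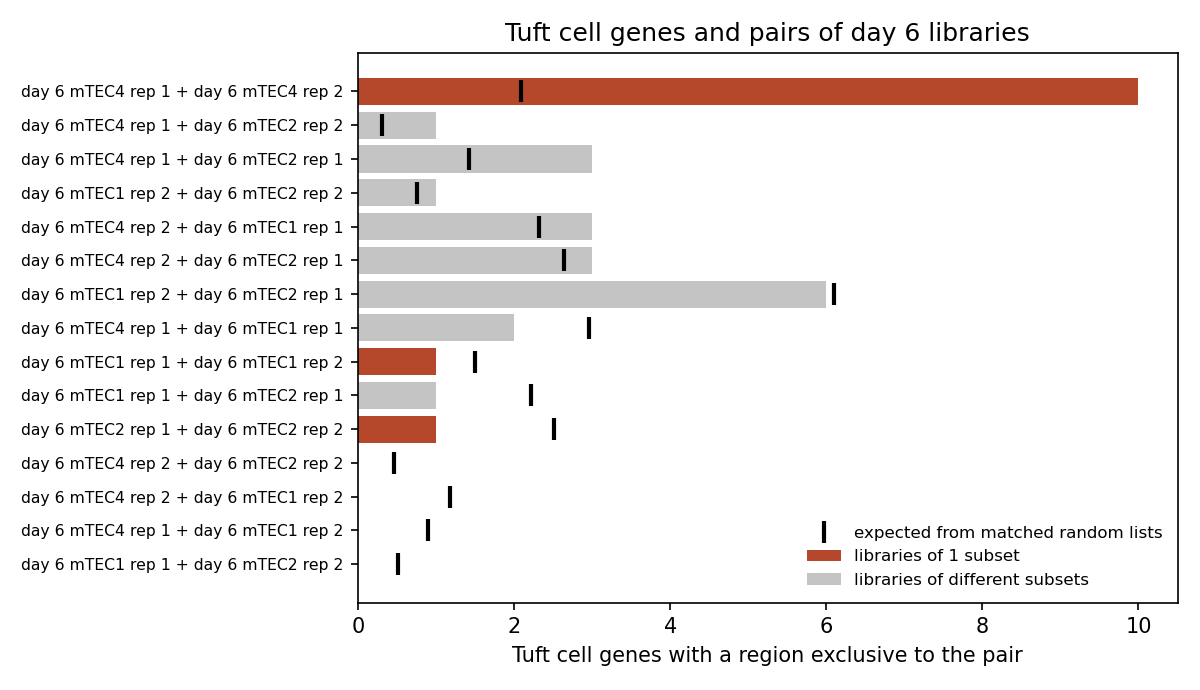
Tuft cell genes with a region exclusive to 2 of the 6 day 6 libraries, over the number expected, for each of the 15 choices of 2. The labelled mTEC4 pair has the highest ratio at 4.77, and the next has 3.20.

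Other listed genes with mTEC4-specific regions included the epithelial genes Epcam and Krt18, Pdgfra and Reg3g, with 2 each. Eef1a1, Elf3, Ehf, Itga6, Chga, Six4, Ciita and Tnfrsf11a had 1 each. The strongest mTEC4-specific regions lay nearest to Pigk, St6gal2, Mat2b, Zbtb10, Edil3, Zfp386, Agap1, Tfap2a, Ppp1r14bl and Ncl. On the list scores mTEC4 stood at an unadjusted exact permutation p of 0.0222 for organogenesis factors (-0.93 against the other 8 libraries, n = 2) and for Ccl21a-high genes (-0.73). The Aire-stage list differed by -0.56 (exact permutation p = 0.0444, n = 2). The tuft cell list scored 0.09 and 0.46 in the mTEC4 libraries, a difference of 0.43 (exact permutation p = 0.133, adjusted p = 0.338, n = 2). No list passed after adjustment in this exact permutation test, where 0 of 22 did and 3 had an unadjusted p under 0.05.

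In mTEC1, specific regions lay nearest to 3 of 10 Ccl21a-high genes with a background region, against 1.30 expected, which was not past its test (one-sided permutation with random lists, p = 0.13, adjusted p = 1). One lay at a boundary of Ccl21a on chromosome 4 at 42773775 to 42774250 and was also called in 3 embryonic lists. Another lay at a boundary of Pdpn, which encodes podoplanin, on chromosome 4 at 143299061 to 143300065, and was called in all 4 embryonic lists. The nearest to Aire lay 4923 bp from the gene on chromosome 10 at 78024725 to 78025098. Cdh5, Emcn and Stxbp5l had 2 specific regions each, and Hoxa3, Eya1, Mki67, Twist2, Alox5ap, Alb and Tnfaip2 had 1 each. The strongest lay nearest to Ighmbp2 (chromosome 19, 3205657 to 3205842), Sult2a4, Gucy1b2, Nr1h2, Gsdmc, Atg5, Gm272, Rbms3, Fam174a and Ankrd44. Of the list enrichments 0 passed and 0 had an unadjusted p under 0.05 (random lists). Of the list scores 0 passed and 1 had an unadjusted exact permutation p under 0.05, the ciliated list at -0.31 (p = 0.0444, n = 2).

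In mTEC2, 66.8% of specific regions were called in at least 3 embryonic lists, against 4.99% for mTEC4, 9.87% for mTEC1 and 24.8% of all regions. Regions exclusive to mTEC1 replicate 2 with mTEC2 replicate 1 reached 71.6%, so a high share was not limited to the labelled mTEC2 pair. That pair also includes an mTEC2 library, while mTEC4 replicate 1 with mTEC1 replicate 1 had 0.61%. Whether a high share is particular to mTEC2 therefore stays open. Mki67, a proliferation marker gene, and Bcl11b had 3 mTEC2-specific regions each, and Myh3, Ywhaz and the T cell gene Cd2 had 2 each. The strongest region counted for Mki67 lay 85954 bp from that gene. Ttn, Foxa2, Tek, Sdha, Apoe, Nfkb1, Zap70, Pdgfrb and Col1a2 had 1 each. The strongest of all mTEC2-specific regions lay 1435 bp from C1s1 on chromosome 6 at 124528778 to 124528908. The next were nearest to Sec11c, Zfp217, Sis, Itgav, Atp1b1, Elavl1, Sucla2, Spin1 and Slco1a5. Thymocyte genes had specific regions at 6 of 18 genes against 2.73 expected (one-sided permutation with random lists, p = 0.0265, adjusted p = 0.329). Of the list enrichments 0 passed and 2 had an unadjusted p under 0.05. The thymocyte list score was 0.67 in mTEC2 against -0.12 in the other libraries, a difference of 0.78 with an exact permutation p of 0.0444 (n = 2), the 1 list of 22 with an unadjusted p under 0.05, and 0 passed.

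The fractions had 3124 (mTEC4), 2321 (mTEC1) and 3010 (mTEC2) specific regions, and the counts did not set them apart from other pairs of day 6 libraries. Among the 15 choices of 2 libraries they ranked 5, 8 and 7, at equal list lengths 4, 9 and 3, and the largest counts belonged to mTEC1 replicate 2 with mTEC2 replicate 1 (7959) and mTEC4 replicate 1 with mTEC1 replicate 1 (5742). Boundaries held 2.24%, 2.71% and 6.11% of the specific regions, against 6.44% of all regions. With peaks of a −log10 q of at least 5 the counts were 46, 62 and 285, and with the 4375 strongest peaks 105, 104 and 141. Leaving out a library of the fraction itself gave 30266 and 34607 regions for mTEC4 (without replicate 1 and replicate 2), 25332 and 37052 for mTEC1, and 13642 and 48253 for mTEC2. Without mTEC1 replicate 1 mTEC4 had 5507, without mTEC1 replicate 2 mTEC2 had 5815, and without mTEC2 replicate 1 mTEC1 had 3937.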

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

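In this part no test was chosen after a result was seen. Single libraries far from the others of their age were sought with Dixon's test on 58 sets of library values, where chance alone gives about 5%, or 2.9, and 5 were found, so the pattern of these 5 is near what chance gives. The median peak width of mTEC1 replicate 1 was 135 bp, against 115 bp for the nearest other day 6 library. Chromosome Y held 144 peaks in E17 replicate 2, against 101 in the nearest embryonic library. The Foxn1 window held 24 regions in E17 replicate 2, the longest list, against 19 in the nearest embryonic library. The Aire-stage list scored -0.71 in mTEC4 replicate 1, against -0.08 in the nearest day 6 library. The post-Aire keratinocyte-like list scored -0.065 in mTEC2 replicate 2, against -0.56 in the nearest day 6 library.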

How the results depend on the processing

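Equal numbers of strongest peaks, autosomes only, and leaving out mTEC4 replicate 1 and mTEC1 replicate 1 together were tests chosen only after results were seen, as were leaving out libraries and the replicate block at Foxn1. Read depth is unknown, and shorter lists limit what absence of a region can show. Over all settings 250 values of the main results kept their side of the threshold or, for counts, lay within 1.5 times, while 61 moved further, 4 fell short of the threshold, 1 passed it and 1 that had passed, the Foxn1 difference, changed direction. Of single list scores 371 kept their side, 80 fell short, 22 passed and 2 that had passed, both of the dendritic cell and macrophage list, changed direction. Values short of the threshold with and without the change, such as the boundary share and the thymocyte score, also changed sign in some settings and are counted as having kept their side. The same-group overlap lost its call only where single libraries were left out, and autosomes alone moved no main count by over 1.5 times. With a −log10 q of at least 5 there were 8 day-6-only, 704 E15-only, 46 mTEC4, 62 mTEC1 and 285 mTEC2 regions, a boundary share difference of -27.5 points, 13 list scores past the threshold, and 0 enriched lists for embryonic-only and mTEC4 regions. With equal list lengths there were 3022 embryonic-only, 2876 E17-only, 1582 mTEC4 and 838 mTEC1 regions, a Foxn1 difference of 2.08, 3 list scores past the threshold and 0 enriched lists for embryonic-only regions. With the 4375 strongest peaks there were 143 embryonic-only, 72 day-6-only, 1308 E15-only, 1026 E17-only, 105 mTEC4, 104 mTEC1 and 141 mTEC2 regions, a Foxn1 difference of -0.25, a boundary share difference of -13.1 points (permutation p = 0.205), 3 list scores past the threshold, a dendritic cell and macrophage difference of 0.37 (adjusted permutation p = 0.116) and 0 enriched lists for mTEC4. With a 50% cover there were 24 day-6-only, 7647 E17-only and 1437 mTEC2 regions. Gene boundaries alone gave 0 list scores past the threshold and a dendritic cell and macrophage difference of 0.13 (adjusted permutation p = 0.467). Adding 0.5 gave 11 list scores, and genes within 25 kb gave 0 enriched lists for embryonic-only regions. Without mTEC4 replicate 1 and mTEC1 replicate 1 together there were 387 day-6-only, 36218 mTEC4 and 27838 mTEC1 regions and 0 list scores past the threshold. Of these changes the cause was not tested, except that shorter lists hold fewer regions, and a fraction with 1 library left has more regions of its own.

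Leaving out 1 library gave same-group differences of 6.68 to 15.5 points, 15212 to 23931 embryonic-only, 164 to 596 day-6-only, 2070 to 14240 E15-only and 5071 to 47910 E17-only regions. It gave 3124 to 34607 mTEC4, 2321 to 37052 mTEC1 and 3010 to 48253 mTEC2 regions, boundary share differences of -1.48 to 0.837 points, Foxn1 differences of 10.7 to 13.6 regions, and 0 to 8 list scores past the threshold. The list contrasts of single groups, where 1 list cannot pass alone, were not read for stability. Motif scores and their alternatives were not run, having no genome sequence.

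Replicate numbers recur in every group but did not pair the libraries: the correlations of 10 pairs of groups ran from -0.0829 to 0.0761, 0 lay above 0.1, and 4 of 10 libraries were closest to one with their own number. Permuting within this replicate block left 0 list scores past the threshold (adjusted permutation p = 0.055 for each of the 7), with fewer arrangements. It left the Foxn1 difference at 12.1 (permutation p = 0.02), the boundary share at -0.684 points (permutation p = 0.8) and the share of splits as large at 0.01.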

Other observations

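The tests chosen only after results were seen are those of sharing by sequence covered, of swapped labels, of background in both pairs of day 6 libraries, of weak peaks behind the thymocyte score, of tuft genes over all day 6 pairs, and the matching on peak strength and width. A pair of T cell loci, chosen after their values were seen, had regions at day 6 alone. Cd8b1, which encodes a chain of the CD8 co-receptor, had 0 regions in all 4 embryonic libraries and 3 ± 2.28 in day 6 libraries (SD, n = 6), with 6 in mTEC2 replicate 1 and 0 in mTEC2 replicate 2. Il7r, the interleukin 7 receptor gene, had 0 regions and 1.83 ± 1.17. Rgs13, of the tuft cell list, had 0 and 1.5 ± 0.837 regions, and the chemokine gene Ccl20 had 1 region in each embryonic library and 0 at day 6. These genes were not tested singly.

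The strongest regions of some sets were very narrow. The 3 leading day-6-only regions, near Ppp2r2b, Gm35315 and Epha3, were 86, 78 and 85 bp wide, and the 6 leading E15-only regions, near Immp2l, Map3k7, Fam241a, Ccng2, Mkx and Cenpw, were 76 to 82 bp wide and were called in all 6 day 6 lists too.

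A hypothesis of the present work is that mTEC4 includes cells with open tuft cell loci. The mTEC4 pair ranked 1 of the 15 choices of 2 day 6 libraries by tuft genes with an exclusive region. It stood at 4.77 times the expected number and the next choice at 3.20 (one-sided permutation with random lists, p = 0.268), so pairs in general did not give as many. The tuft list was singled out for its enrichment in the mTEC4 pair, so this rank is no separate support for the hypothesis. Another list of 10 tuft genes did not extend the pattern. Its score in mTEC4 minus the other 8 libraries was -0.0031 (exact two-sided permutation p = 0.978, n = 2). The main tuft list's difference of 0.43 was itself not past its test (exact permutation p = 0.133, n = 2). Taken as an exact value, 0.43 lay outside what the other list allowed (exact permutation p = 0.0444 for the other list). The other list had mTEC4-specific regions at 3 of 8 genes against 1.40 expected (one-sided permutation with random lists, p = 0.147). A tuft cell signal may therefore hold for part of the tuft genes, in weak peaks, and was not shown for tuft loci in general. Of all mTEC4-specific regions 4.99% were called in at least 3 embryonic lists, and a low share could also hold for regions open in mTEC4 alone. On chromosome X lay 6.66%, against at most 2.47% of any embryonic list. The mTEC4 lists themselves held 6.38% and 5.07% there, and all regions 4.73%. Background peaks stay a candidate explanation for that set as a whole, which these measures do not decide.

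Day 6 libraries missed weaker embryonic regions more often than stronger ones, with 49.99% of the lowest of 5 equal bins of embryonic strength called in no day 6 list but 1.37% of the highest. For lists weaker throughout, the prediction was a like loss at and away from gene boundaries. This was not met, as in the highest bin 0.135% were lost at boundaries and 2.18% away from them. There 7 boundary regions were lost (exact interval 2.82 to 14.4), against 91.8 expected after matching on strength and 25.7 after matching on strength and width. Over all bins 1163 (1100 to 1229) were lost against 1718 after matching on both, a smaller ratio of 1.48. Strength was that in the embryonic lists and width took up much of the excess, so these losses do not exclude weaker lists. Chance sharing is argued against, since at least 18.9% of the weak peaks of each day 6 list lay in regions of all 4 embryonic lists, which cover 1.28% of the sequence. An earlier form of this test, comparing strong with weak peaks, was undecided at ratios of 1.37 to 3.93. For the count of separating regions chance is argued against, as 1 of 100 splits, the real one, gave 15232 and the highest other gave 5170. A share of 1 in 100 is the smallest these splits can give, and they rearrange libraries that may be technical replicates. The count also follows list length. A loss of weaker distal peaks with depth, or a difference of age or fraction, may each contribute and were not tested.

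Some day 6 pairs from different fractions shared more exclusive regions (5742 and 7959 in the 2 highest) than the pairs of 1 fraction (2321 to 3124), while others shared fewer, down to 424. A swap of 2 labels stays open: pairing mTEC4 with mTEC1 by replicate number gave a smallest overlap of 17.7% against 17.4% as labelled, and a smallest count of 1001 against 838 at equal list lengths, 76 against 46 for strong peaks and 129 against 104 for the 4375 strongest. With whole lists the smallest count was 1456 against 2321. Tuft genes stood at 4.77 times the expected number in the labelled mTEC4 pair against 0.675 and 0 in the swapped pairs. The tuft list had been singled out for its result in the labelled pair, so these ratios do not decide on a swap. For mTEC4 replicate 1 with mTEC1 replicate 1, background peaks are a candidate explanation: 0.61% of their 5742 regions were called in at least 3 embryonic lists and 8.83% lay on chromosome X, against at most 2.47% of any embryonic list. Their own lists held 6.38% and 6.36% there. Regions open only at day 6 would also be rare in embryonic lists, so these measures do not decide. For mTEC1 replicate 2 with mTEC2 replicate 1, background is argued against, as 71.6% of their 7959 regions were called in at least 3 embryonic lists, and whether those come from shared cells or from depth was not tested.

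The thymocyte list scored 0.68 higher at day 6 before adjustment. Another list of 20 thymocyte genes, sharing none with it, differed by -0.0078 (exact two-sided permutation p = 0.981), so the rise predicted from thymocyte DNA was not seen. A difference of 0.68 lay outside what it allowed (exact permutation p = 0.0143). This other list already scored 0.58 in embryonic libraries, against -0.37 for the main list. A small share of thymocyte DNA might therefore leave it unchanged, and the result does not decide on thymocyte DNA in the day 6 libraries. Among peaks with a −log10 q of at least 5 the difference was -0.080 (exact permutation p = 0.786), so the higher score was not seen in strong peaks. This filter removes weak peaks of any origin and does not tell background from a small share of thymocyte DNA. It also left little to compare, as 0 thymocyte genes were nearest to a strong region called in both libraries of a day 6 fraction. A difference in strong peaks could therefore have been missed. Thymocyte DNA in single libraries also stays open, since the other list scored 0.94 in mTEC1 replicate 2 and 1.02 in mTEC2 replicate 1. These lay above the 0.44 to 0.71 of the embryonic libraries, while mTEC2 replicate 2 at 0.71 did not and the other 3 lay below, at 0.17 to 0.38.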
